A study of Mus musculus with 7 samples.

How the data were processed

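Messenger RNA was sequenced from mouse placentas of the C57BL/6 strain collected at E10.5, 3 of wild type and 4 lacking the miR-290 microRNA cluster. Per the labels' protocols, RNA was purified on Qiagen miRNeasy micro columns and libraries were made with a stranded KAPA kit for messenger RNA. Whether strand was used when reads were assigned to transcripts is not given in the sources used here, so reads of overlapping and antisense genes may have been shared. The labels give genotype, a replicate number and a library number for each sample and give no litter, sex, batch or dissection details.

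The deposited table holds estimated counts per transcript (expected counts that need not be whole), not scaled to library size or transcript length, per the file headers. The submitters' processing notes name kallisto, a pseudoaligner that divides reads among similar transcripts, and sleuth, a transcript test, with the builds mm10 and GRCm38; their versions are not given in the sources used here. A second copy of the estimated counts deposited without gene names held identical values and was not used further. The authors' deposited comparison table gives a p-value and a q-value for each transcript, and its effect sizes and their standard errors are on a natural log scale, per the file headers. The sign of those effects was settled from the counts: across 35386 transcripts they had a Pearson r of -0.874 with the log2 fold change of knockout over wild type, so their sign was turned to read knockout minus wild type. Genes are not independent replicates in that correlation, which served only to settle the sign.

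Of the 88198 transcripts in the table, 1539 carried no gene name. They held 0.639% to 0.744% of each library's counts and were left out of library sizes and tests. The remaining estimated counts were summed to 30352 genes and rounded to whole numbers; 29.7% of the gene sums were not whole before rounding. Gene identifiers, coordinates and 3′ untranslated regions came from GENCODE release M21 on GRCm38, which held 97.54% of the transcripts and 30202 of the genes. Libraries held 19793382 to 28651465 estimated counts. The genes whose copies are nearly identical (the Prl2c, Prl3d, Psg, Ceacam and Gzm families) depend on how kallisto divided shared reads, and single members of them are uncertain.

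Low-count genes were removed with edgeR's filterByExpr, which left 14970 genes. Genotypes were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, genotype as the only term, 5 residual degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were computed from the fold change and its F statistic. Levels are CPM, read counts scaled to a common library total after TMM, given as mean ± SD. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), again with a correlation estimated from the data, and with fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. A list score is the mean log2 CPM of a list's measured members, and scores were compared by exact permutation over the 35 ways of dividing 7 samples into 3 and 4, for which the smallest possible two-sided p is 0.0286.

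Before the data were examined, 22 gene lists were fixed: placental cell types (spongiotrophoblast, trophoblast giant cell, glycogen trophoblast, labyrinth and syncytiotrophoblast, trophoblast progenitor, endothelium, allantoic mesenchyme, fetal erythroid), neighbouring tissues (maternal decidua, uterine natural killer cell, macrophage, yolk sac endoderm), processes (nutrient transport, imprinted growth genes, proliferation, hypoxia, p53 response, dissociation stress), reported targets of the miR-290 and miR-302 families, genes beside the cluster, the cluster itself and sex-linked genes. The 20 lists with at least 5 measured members that stand for a tissue, a process or a set of targets were tested; the cluster itself and the sex-linked genes were not. The samples, the tests, these lists, the naming rule and most of the alternatives were all set at that time. Lists of steroid hormone synthesis and cholesterol synthesis genes were written after the gene results had been seen.

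Genes were named by a fixed rule: the measured cluster members, the genes directly beside the cluster and the reported targets; the 10 largest log2 fold changes in each direction among genes past the threshold with a mean of at least 1 CPM; up to 4 members with the smallest p in each list; and any gene with a sample far from its group. The rule named 105 genes, of which 75 passed the test. Any other gene given by name was chosen after its values were seen.

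Sites matching the AAGUGC seed shared by miR-291a-3p, miR-294 and miR-295 (AGCACTT, or GCACTTA) were searched in the 3′ untranslated region of each gene's most abundant coding transcript. Genes with a site were compared with the other tested genes that have an annotated 3′ untranslated region by camera. AGCACTT was ranked by the t statistic of its effect (the effect over its standard error) among 630 heptamers of the same base composition, with untranslated region length and base content in the model.

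The scripts were tested on simulated counts drawn from the means and library sizes of these samples. In the simulated comparison of knockout with wild type over 14770 genes, 67 of 100 genes changed 2-fold and 97 of 100 changed 4-fold were recovered, with 7 false calls among 171. A simulated list of 20 shifted genes passed camera at 0.05, as did 6 of 100 unshifted lists. Genes were drawn independently of each other in the simulation, whereas the estimated correlation within the fixed lists was up to 0.73. The simulation therefore does not show how often camera with the preset correlation calls unshifted lists of correlated genes. The seed test passed when a shift was simulated and did not pass without it. That simulated shift was larger than the difference found in the data, so it does not show that a shift as small could be detected.

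Alternatives covered the scaling (DESeq2 size factors, library size only), the tool (DESeq2 1.42.0, limma-voom), the filter on low counts, transcripts tested singly, the replicate number as a block, Y-linked and decidua scores as covariates, fetal erythroid genes left out, each library left out in turn, and the threshold. Protein-coding transcripts only, the joint omission of the libraries with the lowest and the highest decidua score, the decidua covariate in the seed test and the longest annotated untranslated region were added after the data had been seen. For the Ceacam and Prl members of the spongiotrophoblast list, the share of 31-base stretches also present in transcripts of other genes was counted in the GENCODE M21 transcripts on either strand. The cluster's own transcripts were not analysed here. Nlrp12, beside the cluster, had too few counts to be tested. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.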

Results

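Placental transcriptomes were measured in 7 mouse samples, 3 of wild type and 4 of miR-290 knockout, all collected at E10.5, in mid-gestation. The miR-290 cluster encodes microRNAs that are abundant in the early embryo and in trophoblast, and the comparison asks which placental transcripts differ when it is lost. Wild-type libraries held 28651465, 20204174 and 21577934 estimated counts in replicates 1 to 3 (mean 23477858 ± 4532821, SD, n = 3). Knockout libraries held 23100082, 22244043, 19793382 and 20372986 in replicates 1 to 4 (mean 21377623 ± 1553133, SD, n = 4). No pair of libraries matched within sampling noise. The chi-square of paired counts was 15.1 to 49.9 per degree of freedom within groups. The labels do not say that the replicates are separate animals, so p-values measure the spread between these samples, which could be technical in part.

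The targeted locus lies on chromosome 7, where the annotation places 9 microRNA genes of the cluster between 3218626 and 3220841 (GRCm38, GENCODE M21). The cluster's own transcripts were not analysed here, so loss of the microRNAs was not checked in these libraries. AU018091, the gene directly beside it (ENSMUSG00000054753.9, chromosome 7, 3154658 to 3169203, minus strand), was measured at 58.7 ± 7.09 CPM in wild type (SD, n = 3) and 63.7 ± 7.14 CPM in knockout (SD, n = 4), a log2 fold change of 0.12 (SE 0.113) that did not pass the test. Of 13 measured genes on the list around the cluster, Myadm (log2 fold change 0.73) and Prkcg (1.02) rose, Tmc4 (-0.35) and Prpf31 (-0.32) fell, and 9 did not pass. Prkcg overlaps Myadm on the same strand and was low beside it (wild-type means of 0.748 and 286 CPM). Its call may thus rest in part on reads of Myadm, which was not tested. Adjusted over the list alone, 2 rose and 2 fell. The list's median was 0.03 and became -0.08 when libraries were scaled by size only and -0.01 without knockout replicate 1 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.776).

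Knockout placentas held lower levels of most spongiotrophoblast genes, while trophoblast giant cell genes moved both ways. In all, 2424 of 14970 genes passed edgeR's quasi-likelihood test at an adjusted p of 0.05, 1486 higher and 938 lower in knockout, so that 61.3% of them were higher. Among them 141 rose and 26 fell by more than 4-fold. The balance between directions depended on scaling: with library size only, 3048 genes passed and 39.5% were higher, as the median log2 fold change of all genes moved from -0.02 to -0.14. The groups did not overlap in 2412 of the 2424 genes. They did not overlap in 4954 of all tested genes (33.1%), where chance gives 5.71%. The first principal component of the 1000 most variable genes held 54.5% of the variance. Some libraries weighed heavily on the count, which was 565 without wild-type replicate 1, 1241 without wild-type replicate 2, 1443 without wild-type replicate 3, 829 without knockout replicate 2, 1527 without knockout replicate 1 and 1606 without knockout replicate 4. The count was 315 with the maternal decidua score as a covariate, and that score was 4.38 ± 0.32 in wild type (SD, n = 3) and 5.04 ± 0.56 in knockout (SD, n = 4) on the log2 scale.

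Among the leading genes that rose was Hsd3b6, a hydroxysteroid dehydrogenase of steroid hormone synthesis (ENSMUSG00000027869.14, chromosome 3, 98805504 to 98814443). It went from 23.5 ± 9.10 CPM (SD, n = 3) to 520 ± 187 CPM (SD, n = 4), a log2 fold change of 4.47 (SE 0.437; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00587), and was higher in 4 of 4 knockout libraries than in any wild-type library. Endou, a placental endoribonuclease, rose with a log2 fold change of 5.02 (SE 0.779), Doxl2 rose from 2.49 ± 0.994 to 57.8 ± 25.9 CPM, and Igfbpl1, a protein related to insulin-like growth factor binding proteins, from 0.388 ± 0.399 to 19.5 ± 7.99 CPM. Gm9513 (log2 fold change 6.84), Ankk1 (5.22), D730001G18Rik (4.76) and Gm9573 (4.27) also rose from wild-type means of under 1 CPM. Gm7257 had 2 counts over all wild-type libraries and 602 over the knockout libraries, a ratio of 270 with a 95% exact counting interval of 74.4 to 2233. That interval covers counting error only.

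The genes with the largest falls were mostly pregnancy-specific glycoproteins and their Ceacam relatives, secreted or surface proteins of trophoblast. Psg21 (ENSMUSG00000070796.11, chromosome 7, 18646736 to 18656725) went from 110 ± 78.6 CPM (SD, n = 3) to 8.02 ± 2.94 CPM (SD, n = 4), a log2 fold change of -3.79 (SE 0.479; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00619), and was lower in 4 of 4 knockout libraries. Ceacam14 (-3.91), Prl8a8 (-3.90), Ceacam12 (-3.73), Prl7a2 (-3.26), Psg23 (-3.21), Psg27 (-3.09), Psg-ps1 (-2.80) and Psg25 (-2.66) fell as well. The lowest log2 fold change, -4.60, belonged to Gm10925 (chromosome 1, 24613974 to 24614651), at 175 ± 56.3 CPM in wild type (SD, n = 3) and 7.21 ± 12.3 CPM in knockout (SD, n = 4). All 678 bases of this pseudogene are identical to the mitochondrial gene mt-Atp6, so reads of the copies cannot be assigned to either by sequence and its call is no evidence of a change at the chromosome 1 gene.

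**Figure D1:**
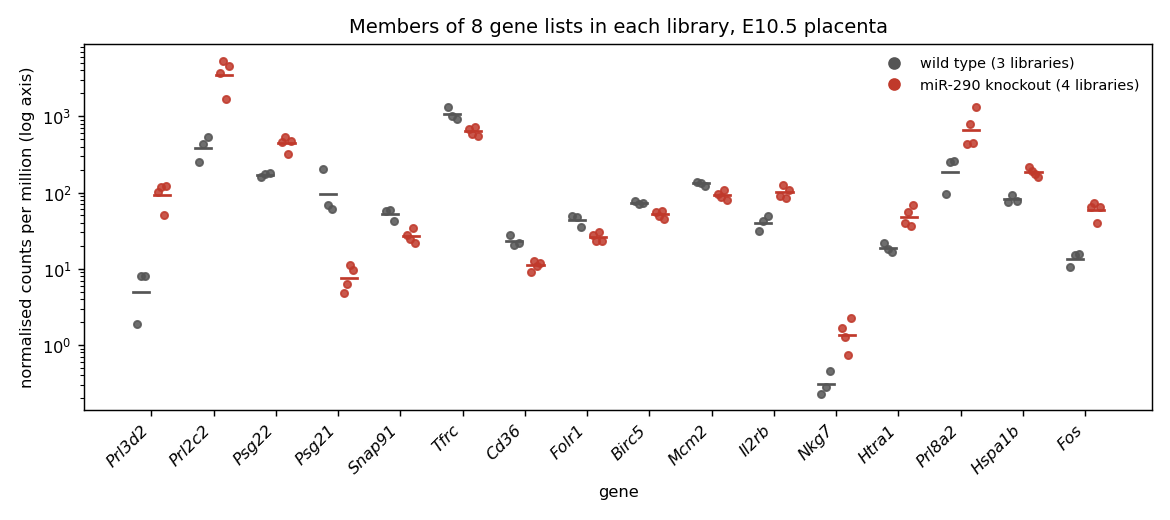
Normalised read counts (CPM) on a log axis for 16 genes, the 2 named members with the smallest p of 8 gene lists, with a point for each of 3 wild-type and 4 knockout libraries and a bar at the geometric mean of each group. Psg21 goes from a mean of 110 to 8.02 CPM and Prl2c2 from 406 to 3824 CPM, while Psg22 moves opposite to Psg21, from 171 to 449 CPM.

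Spongiotrophoblast genes, which mark the layer between giant cells and labyrinth, were lower as a group. Of 17 measured members 14 fell, 1 rose and 2 did not pass, and the counts were the same when adjusted over the list alone. The list score went from 5.49 ± 0.68 (SD, n = 3) to 3.64 ± 0.32 (SD, n = 4) and was below every wild-type library in 4 of 4 knockout libraries. Outside the naming rule and chosen after their values were seen, the layer's usual marker Tpbpa fell by 0.89 on the log2 scale (2472 ± 617 to 1339 ± 257 CPM), its relative Tpbpb by 2.35, and Flt1, a receptor of vascular endothelial growth factor, by 0.83. Psg22 was the member that rose, with a log2 fold change of 1.39 (171 ± 11.7 to 449 ± 89.5 CPM). Camera with Benjamini-Hochberg adjustment gave a median log2 fold change of -2.08 and adjusted p = 4.68e-07, and adjusted p = 0.538 with an estimated correlation. The summed counts of the 6 Psg members on the list had a log2 fold change of 0.02 (SE 0.227), so the fall of single Psg members did not extend to their sum. Without wild-type replicate 1, 8 members fell, as also without knockout replicate 2; with the decidua score as a covariate edgeR called 1 higher and 0 lower, with 13 lower at an unadjusted p of 0.05, while the median was -1.91.

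Trophoblast giant cell genes moved both ways. Of 20 measured members 9 rose, 3 fell and 8 did not pass; adjusted over the list alone, 11 rose and 3 fell. Prl2c2, a proliferin (ENSMUSG00000079092.3, chromosome 13, 12996125 to 13005383), rose from 406 ± 142 CPM (SD, n = 3) to 3824 ± 1580 CPM (SD, n = 4), a log2 fold change of 3.24 (SE 0.437). The placental lactogen I copies Prl3d2 (log2 fold change 4.05) and Prl3d3 (3.83) rose, as did, chosen after their values were seen, Prl3d1 (3.71, from 265 ± 185 to 3458 ± 1050 CPM), Prl7a1 (3.15) and the transcription factor Hand1 (0.74). The 3 that fell were Prl7a2 and, chosen in the same way, the cathepsins Ctsm (-2.63) and Ctsq (-1.14), of which Ctsq marks the sinusoidal giant cells of the labyrinth. The list score was 5.86 ± 0.41 in wild type (SD, n = 3) and 6.96 ± 0.22 in knockout (SD, n = 4), higher in 4 of 4 knockout libraries (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00346, and adjusted p = 0.538 with an estimated correlation). The number that rose was 6 without wild-type replicate 1 and 3 with the decidua score as a covariate, where the median of the list went from 0.58 to 0.38. Reads of the Prl3d copies and of the Prl2c copies can be exchanged, so the single members are uncertain.

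Genes of the labyrinth and syncytiotrophoblast, where exchange with maternal blood takes place, were lower in smaller steps. Of 20 measured members 6 fell, 1 rose and 13 did not pass; adjusted over the list alone, 11 fell and 1 rose. Snap91 (log2 fold change -0.97), the transferrin receptor Tfrc (-0.75, from 1074 ± 207 to 638 ± 79.1 CPM), the monocarboxylate transporter Slc16a1 (-0.59) and the regulator Pparg (-0.34) fell. The score was lower in 4 of 4 knockout libraries (camera with Benjamini-Hochberg adjustment, median log2 fold change -0.48, adjusted p = 0.00148, and adjusted p = 0.538 with an estimated correlation). Nutrient transport genes, 4 of which are also on the labyrinth list, showed 13 of 45 members that fell, 2 that rose and 30 that did not pass; adjusted over the list alone, 18 fell and 3 rose. Cd36, a fatty acid carrier, fell by 1.05 on the log2 scale, the folate receptor Folr1 by 0.76 and the amino acid transporter Slc38a4 by 0.52 (camera with Benjamini-Hochberg adjustment, median -0.22, adjusted p = 0.00418, and adjusted p = 0.538 with an estimated correlation). The labyrinth and transport counts that fell were 3 and 3 without wild-type replicate 2 and 2 and 4 without knockout replicate 2, and 8 transport members fell without knockout replicate 4. The transport median was -0.14 without wild-type replicate 2. Without wild-type replicate 1, and again with the decidua score (higher in knockout, 5.04 against 4.38) as a covariate, 1 transport member fell and edgeR called 0 labyrinth members lower, each time with 6 at an unadjusted p of 0.05. The covariate moved the labyrinth median from -0.48 to -0.19.

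Cell division genes were lower by a small amount. Of 30 measured members 15 fell and 15 did not pass; adjusted over the list alone, 21 fell. Birc5 (log2 fold change -0.49), Mcm2 (-0.52), Kif11 (-0.52) and Kif20a (-0.49), which act in mitosis or DNA replication, fell. The score was 6.74 ± 0.05 in wild type (SD, n = 3) and 6.37 ± 0.16 in knockout (SD, n = 4), lower in 4 of 4 knockout libraries (exact permutation test, two-sided p = 0.0571). Camera with Benjamini-Hochberg adjustment gave a median of -0.41 and adjusted p = 3.65e-08, and adjusted p = 0.538 with an estimated correlation. The number that fell was 7 without wild-type replicate 2, 5 without wild-type replicate 3, 9 without knockout replicate 1 or 4 and 1 without knockout replicate 2. Without wild-type replicate 1 edgeR called 0 members lower, with 18 at an unadjusted p of 0.05. It also called 0 with the decidua score (5.04 in knockout, 4.38 in wild type) as a covariate, with 15 lower at an unadjusted p of 0.05, and the median went from -0.41 to -0.24.

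Trophoblast progenitor and glycogen trophoblast genes had members that moved either way. Of 15 measured progenitor genes, Eomes (log2 fold change 2.43, from 5.46 ± 2.43 to 29.1 ± 8.36 CPM), Esrrb (1.21) and Tead4 (0.53) rose, all of them transcription factors, Epcam (-0.33) and Met (-0.37) fell, and 10 did not pass; adjusted over the list alone, 3 rose and 3 fell. Met was chosen after its value was seen. The progenitor score was 4.44 ± 0.06 in wild type (SD, n = 3) and 4.67 ± 0.06 in knockout (SD, n = 4), higher in 4 of 4 knockout libraries (exact permutation test, two-sided p = 0.0286, the smallest possible), while camera with Benjamini-Hochberg adjustment gave adjusted p = 0.516 for a median of 0.18. The progenitor median was 0.09 without knockout replicate 4 and 0.12 without wild-type replicate 3, and with the decidua covariate 1 member rose and edgeR called 0 lower, with 2 lower at an unadjusted p of 0.05. Of 11 glycogen trophoblast genes Prl6a1 (0.45) rose, Prl2b1 (-0.71) fell and 9 did not pass, with the same counts adjusted over the list alone. The median of 0.06 became -0.05 with library size only and -0.01 without wild-type replicate 1 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.748). For glycogen trophoblast genes edgeR called 0 without wild-type replicate 1 or 3, without knockout replicate 1, 2 or 4, and with the decidua covariate. In each of these settings 1 or 2 were higher and 1 or 2 lower at an unadjusted p of 0.05.

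Genes of uterine natural killer cells, maternal cells next to the placenta, were higher in knockout as a group, and a few decidua and macrophage genes rose. All 13 measured genes of uterine natural killer cells had positive log2 fold changes, 7 rose, 6 did not pass, and 13 rose when adjusted over the list alone. Il2rb, a cytokine receptor subunit (log2 fold change 1.32), Nkg7 (2.20), the pore-forming Prf1 (1.21) and Klrb1b (1.42) rose, and the list score was higher in 4 of 4 knockout libraries (3.47 ± 0.48, SD, n = 3, and 4.71 ± 0.42, SD, n = 4). Camera with Benjamini-Hochberg adjustment gave a median of 1.21 and adjusted p = 2.63e-06, and adjusted p = 0.538 with an estimated correlation. Of 19 maternal decidua genes Prl8a2 (1.88), Htra1 (1.38) and Htra3 (1.46) rose and 16 did not pass; adjusted over the list alone, 3 rose. The decidua score was above every wild-type library in 3 of 4 knockout libraries (exact permutation test, two-sided p = 0.143), and camera with Benjamini-Hochberg adjustment gave a median of 0.90 and adjusted p = 0.0188, and adjusted p = 0.633 with an estimated correlation. The decidua median was 0.44 without knockout replicate 4 and 0.19 without that library and wild-type replicate 1, and the camera call was lost in both cases and without wild-type replicate 1 alone. Of 12 macrophage genes Csf1r (2.21, from 147 ± 21.8 to 681 ± 227 CPM) and Cd14 (2.01) rose and 10 did not pass; adjusted over the list alone, 4 rose (camera with Benjamini-Hochberg adjustment, median 0.53, adjusted p = 0.0543), and the list did not pass. It passed in 5 of 15 alternatives. The macrophage median was 0.05 without knockout replicate 4 and -0.14 with the decidua covariate. Csf1r is known in trophoblast as well as in macrophages. Without wild-type replicate 1 or without wild-type replicate 2 the number that rose was 1 on each of these lists, and without knockout replicate 2 it was 2, 1 and 1 in the order given. Without knockout replicate 4, 2 natural killer cell genes and 1 decidua gene rose, and without wild-type replicate 3, 1 decidua gene rose. With the decidua covariate 1 natural killer cell gene rose, and the median of that list went from 1.21 to 0.57.

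Stress-related genes were higher in the same libraries. On the list of immediate-early and heat shock genes that respond to tissue handling, 9 of 14 members rose, 1 fell and 4 did not pass; adjusted over the list alone, 10 rose and 2 fell. Fos (log2 fold change 2.14), Fosb (2.03), Hspa1a (1.39) and Hspa1b (1.18, from 82.0 ± 9.75 to 185 ± 24.5 CPM) rose, and Btg2, chosen after its value was seen, fell by 0.33 on the log2 scale. The score was 4.25 ± 0.17 in wild type (SD, n = 3) and 5.10 ± 0.17 in knockout (SD, n = 4), higher in 4 of 4 knockout libraries (camera with Benjamini-Hochberg adjustment, median 1.03, adjusted p = 1.87e-04, and adjusted p = 0.538 with an estimated correlation). Of 18 hypoxia genes 4 rose and 14 did not pass, among them Vegfa (0.84), Hk2 (1.02), Egln3 (1.12) and Ndrg1 (0.54) that rose; adjusted over the list alone, 4 rose and 1 fell (camera with Benjamini-Hochberg adjustment, median 0.22, adjusted p = 0.0189, and adjusted p = 0.566 with an estimated correlation). Of 14 p53 response genes Sesn2 (0.52) and Phlda3 (0.43) rose and 12 did not pass; adjusted over the list alone, 4 rose (camera with Benjamini-Hochberg adjustment, median 0.26, adjusted p = 0.0202, and adjusted p = 0.538 with an estimated correlation). The number of hypoxia genes that rose was 2 without wild-type replicate 2, and the hypoxia list lost its call in camera without knockout replicate 1. The stress count was 8 without wild-type replicate 1, while edgeR then called 0 hypoxia and 0 p53 members higher, with 6 and 5 at an unadjusted p of 0.05. With the decidua covariate 7 stress genes rose, and edgeR called 0 hypoxia and 0 p53 members higher, with 6 and 3 at an unadjusted p of 0.05; the p53 median was then 0.11 and its list call in camera was lost. The p53 median was 0.16 without knockout replicate 4.

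Endothelial genes rose in part, and fetal erythroid and allantoic mesenchyme genes did not pass singly. Of 17 endothelial genes 7 rose, 1 fell and 9 did not pass; adjusted over the list alone, 8 rose and 2 fell. Cdh5, the endothelial cadherin (log2 fold change 0.60), Tie1 (0.68) and Esam (0.78) rose and Plvap (-0.57) fell (camera with Benjamini-Hochberg adjustment, median 0.32, adjusted p = 0.0469, and adjusted p = 0.614 with an estimated correlation). With edgeR, 0 of 18 fetal erythroid genes passed, also adjusted over the list alone, against 1 lower at an unadjusted p of 0.05 and 0 with DESeq2 and limma-voom; camera with Benjamini-Hochberg adjustment gave a median of -0.22 and adjusted p = 0.0282, and adjusted p = 0.647 with an estimated correlation. With edgeR, 0 of 16 allantoic mesenchyme genes passed, also adjusted over the list alone, against 3 higher and 3 lower at an unadjusted p of 0.05, 2 higher and 3 lower with DESeq2 and 0 with limma-voom (camera with Benjamini-Hochberg adjustment, median -0.18, adjusted p = 0.491). The number of endothelial genes that rose was 2 without wild-type replicate 2 or 3 or knockout replicate 4, 4 without knockout replicate 1 and 1 without knockout replicate 2, and edgeR called 0 without wild-type replicate 1, with 7 higher at an unadjusted p of 0.05. With the decidua covariate it also called 0, with 5 higher at an unadjusted p of 0.05, the endothelial median went from 0.32 to 0.14 and the erythroid and mesenchyme medians turned to 0.02 and 0.04. The endothelial median was 0.49 without wild-type replicate 3. The mesenchyme median ran from -0.31 without knockout replicate 3 to 0.01 without wild-type replicate 2. EdgeR called 3 mesenchyme members lower without knockout replicate 3 and 1 lower without wild-type replicate 3. The erythroid median was -0.37 without knockout replicate 1, -0.13 without knockout replicate 4 and -0.12 without wild-type replicate 3. Of 15 alternatives (fry and an estimated correlation among them), the list call was lost in 9 for the endothelial list and in 8 for the erythroid list.

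Imprinted growth genes and yolk sac genes were mixed. Of 22 imprinted genes Gnas (log2 fold change 0.79), the growth-restraining receptor Igf2r (0.46) and Sgce (0.33) rose, Slc38a4 (-0.52) and, chosen after its value was seen, Zdbf2 (-0.63) fell, and 17 did not pass; adjusted over the list alone, 4 rose and 7 fell (camera with Benjamini-Hochberg adjustment, median -0.19, adjusted p = 0.149). The imprinted median turned to 0.01 with the decidua covariate and was -0.09 without knockout replicate 4, and the list passed in camera without wild-type replicate 3. Of 18 yolk sac endoderm genes Lama1 (1.04), Thbd (1.41) and Hnf1b (0.67) rose and 15 did not pass, with 3 that rose adjusted over the list alone. Thbd is known in giant cells as well. The yolk sac median was -0.76 and its mean -0.55, while fry gave the opposite sign, and camera with Benjamini-Hochberg adjustment gave adjusted p = 0.802. The sign of the median rested on 1 library, since it was 0.15 without wild-type replicate 2.

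**Figure D2:**
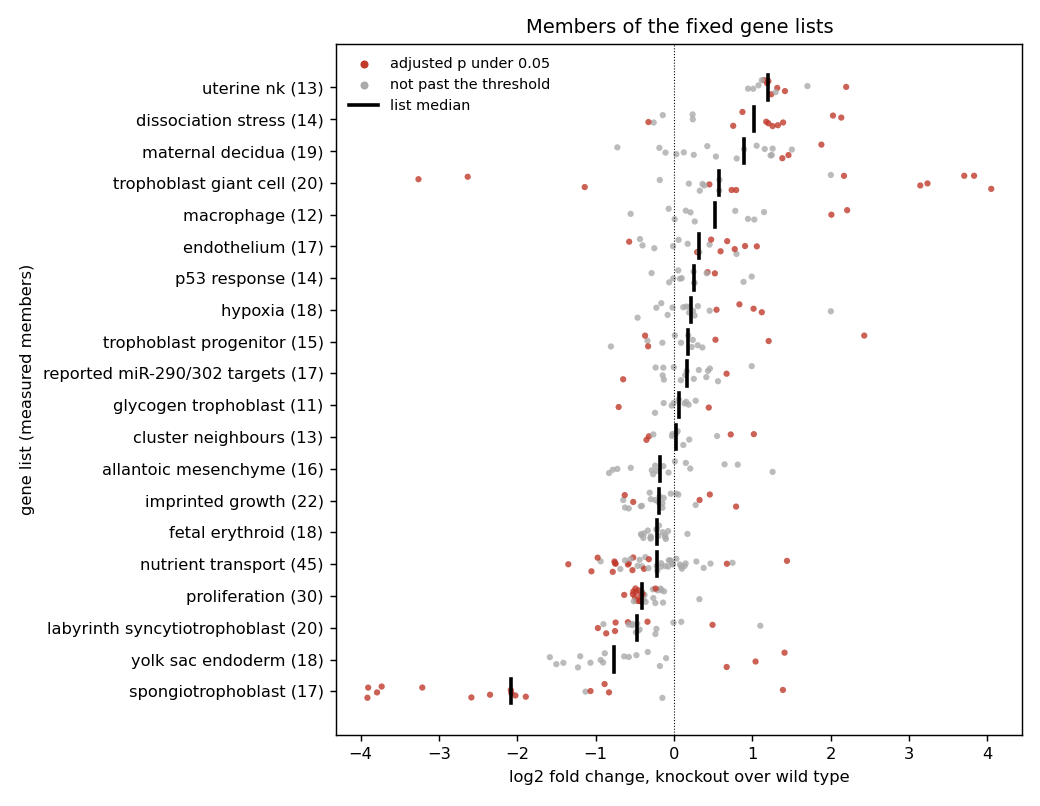
Log2 fold change of knockout over wild type for each measured member of 20 gene lists, with a point per gene, red where its adjusted p passed 0.05, and a bar at the list median. Medians run from -2.08 for spongiotrophoblast to 1.21 for uterine natural killer cell genes, and giant cell genes spread from -3.26 to 4.05.

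Camera called 12 of the 20 lists with the preset correlation. With an estimated correlation it called 0, with 0 at an unadjusted p of 0.05, and fry called 6. The counts of 3 or fewer members on the imprinted, p53, progenitor and cluster lists were 0 to 4 when single libraries were left out.

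A microRNA lowers the transcripts it binds, so its targets would be read first for its loss. Of 17 measured genes reported as targets of the miR-290 and miR-302 families, Nr2f2, a nuclear receptor (ENSMUSG00000030551.14, chromosome 7, 70351944 to 70366735), rose with a log2 fold change of 0.67 (SE 0.147), the Wnt antagonist Dkk1 fell by 0.65 on the log2 scale, and 15 did not pass. Adjusted over the list alone, 5 rose and 2 fell. The cell cycle inhibitor Cdkn1a had a log2 fold change of 0.99 (SE 0.298), Lats2 of 0.41 (SE 0.121), Wee1 of 0.46 (SE 0.134) and Casp2 of -0.23 (SE 0.0676), none of which passed over all genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0563, 0.0523, 0.0524 and 0.0512). As a list the targets had a median of 0.16 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.216). DESeq2 called 5 higher and 2 lower, and edgeR called 4 higher and 0 lower without knockout replicate 3. Without knockout replicate 2 edgeR called 0, with 6 higher and 2 lower at an unadjusted p of 0.05. It also called 0 with the decidua covariate, with 2 higher and 1 lower at an unadjusted p of 0.05, and the median went from 0.16 to 0.07. The log2 fold change was then 0.30 for Cdkn1a, 0.20 for Lats2 and for Wee1, and 0.50 for Nr2f2, which lost its call.

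Genes with a miR-290 seed site in the 3′ untranslated region did not pass the test for a shift. The 2538 genes with a site had a median log2 fold change of 0.00 and the 11540 others one of -0.02, a difference of 0.03. Camera gave p = 0.378, as small as in 8 of 35 splits of the samples in an exact permutation, and p = 0.131 with an estimated correlation. Of the genes with a site 285 rose (11.2%) and 152 fell (5.99%), against 1162 (10.1%) and 773 (6.70%) of the others. The 420 genes with an AGCACTT match followed by A differed by 0.07 (camera with Benjamini-Hochberg adjustment over the 3 seed tests given here, adjusted p = 0.237). Genes with a site have longer untranslated regions (median 2290 against 776 bases), and against genes matched on length and base content the difference was 0.01 (camera with the same adjustment, adjusted p = 0.889). AGCACTT ranked 101 of 630 heptamers of its base composition (effect 0.0161 on the log2 scale). GCACTTA, the other form of the site, ranked 547 with an effect of the opposite sign (-0.0187).

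**Figure D3:**
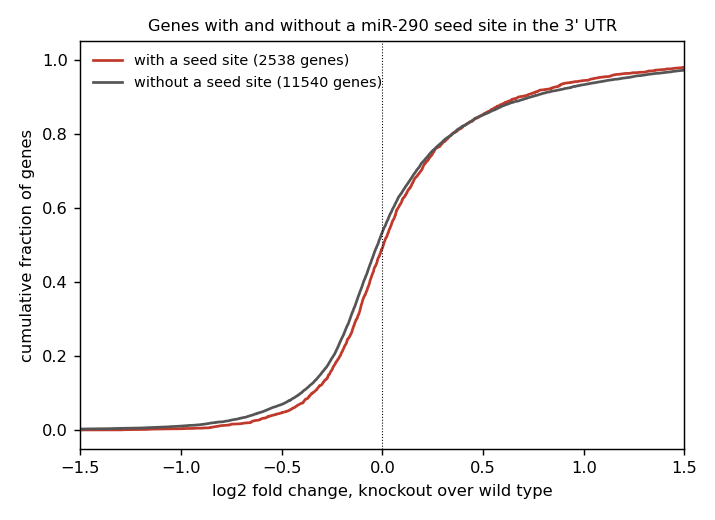
Cumulative fraction of genes against log2 fold change of knockout over wild type, for 2538 genes with a miR-290 seed site in the 3′ untranslated region and 11540 genes without, with the horizontal axis limited to the range drawn. The curves lie close together, with a difference of medians of 0.03.

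The authors' deposited table gave q-values to 39863 transcripts, of which 1863 lay below 0.05, 1309 higher and 554 lower in knockout. In the authors' deposited table Csf1r (effect 1.51 on the natural log scale), Fos (1.48) and Eomes (1.77) were higher and Ceacam14 (-2.60), Cd36 (-0.69) and Birc5 (-0.35) were lower. The transcripts called in the authors' deposited table belonged to 1661 genes, 1507 of which also passed the gene test, where 269 would be shared by independent lists of these sizes; both used the same counts, so the overlap is not independent evidence. The direction was the same in 100% of the transcripts of shared genes in the authors' deposited table. As the sign of that table was settled from these counts, this is no independent evidence either. A further 917 genes passed the gene test without a call in that table.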

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

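The tests of a decidua covariate on the genes that rose and of a gradient between placentas were set before their results were seen; the covariate over all giant cell members and the comparison of libraries with Y-linked reads were chosen after.

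Prl3d3, a giant cell hormone gene, stood at 77.41 CPM in knockout replicate 3, apart from 150.0 to 169.8 CPM in the other knockout libraries. It was the only gene set apart in this way among 128 checks of named genes, list scores and library totals over the 4 knockout libraries, and chance sets apart about 1 in 20 such groups. Reads of Prl3d3 can be exchanged with Prl3d1 and Prl3d2. The smaller rise in this library was not particular to Prl3d3. Prl3d2 stood at 51.31 CPM there (101.9 to 120.2 in the other knockout libraries) and Prl2c2 at 1687 CPM (3703 to 5372). Of the 10 largest rises named, all but D730001G18Rik were lowest in knockout replicate 3 among the knockout libraries. On the first principal component this library stood at 8.14, and the other knockout libraries at 16.28 to 35.97.

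The rise of giant cell genes is the pattern this library bears on. If more maternal tissue in the knockout dissections were the cause, holding the decidua score fixed would lower it. For the 9 genes that rose, the median log2 fold change was 3.15 without the covariate and 2.755 with it (SE 0.428), above the bound of 1.57. The SE of 0.428 is taken over genes, which are not independent replicates, so the margin over the bound does not measure the spread between samples. By the size of the median alone, the result argues against maternal tissue as the whole cause for these genes, though a part of the rise may come from it. They were picked because they rose in these same data, so the result does not carry over to the list. Of the 9 genes, 3 kept their call with the covariate. The fit then had 1 residual degree of freedom fewer and 315 in place of 2424 genes passed, while the median SE of the 9 genes was 0.437 without and 0.434 with it. Over all 20 members, which moved both ways, the median went from 0.58 to 0.377 (SE 0.417, again over genes). That is not above its bound of 0.29 by its SE, so the test cannot decide for the whole list. A gradient of stage or dissection that is not tied to genotype stays open, as wild-type replicate 1 minus replicate 2 correlated across genes with the knockout mean minus wild-type replicate 3 at r = -0.282, between the bounds set for either answer. Loss of the cluster may also account for the rise, and dissections that took more of the maternal face could carry more giant cells together with decidua, which was not tested.

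Y-linked reads were present in wild-type replicate 1 and knockout replicate 3 alone (Ddx3y at 3414 and 1857 counts, 3 to 10 in the others). Across 14379 genes the deviation of wild-type replicate 1 from its group correlated with that of knockout replicate 3 at r = 0.269, and with those of the other knockout libraries at 0.134, -0.147 and -0.204; with 1 such library per genotype, sex and other differences between samples cannot be told apart.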

How the results depend on the processing

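The omission of wild-type replicate 1 with knockout replicate 4 and the restriction to protein-coding transcripts were chosen after the data had been seen. The gene count stayed within 1.5 times of 2424 under DESeq2 size factors (2371), DESeq2 (3402), limma-voom (2445), no filter (2030), a mean CPM of at least 1 (2451), the Y-linked covariate (2805), erythroid genes left out (2439) and protein-coding transcripts (2136). Library size only gave 1843 lower genes. The decidua covariate gave 315 (273 higher, 42 lower), the joint omission of the libraries with the lowest and highest decidua score 390 (319 and 71), an adjusted p of 0.1 as threshold 4081 (2281 and 1800), and transcripts tested singly 229 genes (197 and 35, some in both directions). Leaving out each library gave 565 to 2787 genes, 469 to 1706 higher and 96 to 1081 lower; the lowest of each was without wild-type replicate 1 and the highest without knockout replicate 3. The looser threshold raises the count by construction, and for the others the cause was not tested. Genes called with all samples kept their direction in 100% of cases in every gene-level setting except protein-coding transcripts, with 99.8%. The replicate number as a block, without knockout replicate 4, gave 575 genes (495 higher, 80 lower), 559 of them among the 2424. Deviations of same-numbered samples correlated at 0.119, 0.081 and -0.248, only replicate 2 matched its own number best, and so the numbers were not taken to pair samples. Wild-type replicate 3 matched knockout replicate 4 best. On the second principal component (15% of the variance) they stood at -18.65 and -25.24, and the other libraries at 0.82 to 15.73. The library numbers of wild-type replicate 3 and knockout replicate 4 are consecutive and come after those of all other libraries. What these numbers stand for is not given. Whether the samples so numbered share a litter or batch is not given by the labels, and a block joining them was not tested. Of 75 named genes past the threshold, 22 kept the call with the decidua covariate, 38 with the block, 35 without wild-type replicate 1, 44 without knockout replicate 2, 16 as single transcripts and 71 with library size only. Tmc4 reversed as a single transcript (0.151), and the decidua list under its own covariate (-0.006), which removes it by construction. The estimated correlation called 0 lists and fry 6; leaving out each library gave 9 to 13. The seed difference was 0.022 to 0.034 when each library was left out, and no alternative passed the threshold. At the depth of these libraries 67 of 100 simulated 2-fold changes were recovered, so smaller changes can be missed.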

Other observations

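The lists of steroid and cholesterol synthesis genes and the tests of dilution and of reads shared between copies were chosen after the results had been seen; the counts over other splits, the seed test and the test of genes near the cluster were set before.

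Genes of steroid hormone synthesis, which giant cells are known to express, were higher in knockout. Of 19 measured members 12 rose, 1 fell and 6 did not pass, with the same counts adjusted over the list alone. Star, which brings cholesterol into mitochondria, rose from 103 ± 45.5 CPM (SD, n = 3) to 1261 ± 478 CPM (SD, n = 4), a log2 fold change of 3.61 (SE 0.44). Cyp11a1, the side-chain cleavage enzyme, had a log2 fold change of 3.29, its electron donor Fdx1 of 1.86, the lipoprotein receptor Scarb1 of 2.80 and Cyp17a1 of 1.19, and all rose; Stard3 fell by 0.25 on the log2 scale. The list median was 0.682 and its score was higher in 4 of 4 knockout libraries (camera with Benjamini-Hochberg adjustment, adjusted p = 3.85e-07, and adjusted p = 0.101 with an estimated correlation). The number that rose was 9 without wild-type replicate 1, 10 without knockout replicate 2 or wild-type replicate 2 or 3, and 7 with the decidua covariate. As the list was written after Hsd3b6 had been seen, the rise is not an independent finding.

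Of 24 cholesterol synthesis genes 6 rose and 18 did not pass, with the same counts adjusted over the list alone. Dhcr7 (log2 fold change 1.90, from 35.1 ± 5.12 to 131 ± 29.9 CPM) and Insig1 (0.54) were among those that rose. The list median was 0.103 and turned to -0.016 with library size only (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0124, and adjusted p = 0.101 with an estimated correlation), and 2 members rose without wild-type replicate 1 or with the decidua covariate, 3 without any other single library except knockout replicate 3, and 1 with the replicate block.

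The fall of spongiotrophoblast genes may be technical or biological. Dilution of fetal tissue by maternal tissue would lower all fetal lists alike. The smallest gap between the spongiotrophoblast median and those of the erythroid, mesenchyme and endothelial lists was 1.855 log2 units, to the erythroid list, which argues against dilution as the whole cause. The mesenchyme list is a weaker comparison, as it shares Hoxa11 and Lum with the decidua list. Whether the endothelial genes come from fetal vessels alone was not tested. For reads exchanged between copies, a single prediction over the families was set before its result and divided by family after it: the summed Psg, Ceacam and Prl members had a log2 fold change of -0.387 (SE 0.257), which did not pass. By family, the Ceacam sum had a log2 fold change of -2.368 (SE 0.436), the Prl sum of -2.40 (SE 0.493) and the sum of Tpbpa and Tpbpb of -0.96 (SE 0.204), so exchange within each of these families does not account for their fall. Exchange with genes off the list does not either for Ceacam and Prl. There, 6 of 7 measured members shared no stretch of 31 bases with any gene off the list and Ceacam12 shared 6.75% of them, where at least 62.5% of the reads were lost (2 SE allowed). Exchange between listed members of different families was not tested. The Psg sum was 0.022 (SE 0.227), as Psg22 rose, so for the Psg members exchange of reads stays open beside a change of Psg members used; wild-type replicate 1, with the highest score (6.28 against 5.14 and 5.07), widens the difference.

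For the gene count, 1 of 35 splits of the samples gave as many genes, the real one with 2424, and the highest other gave 1. A chance division of the samples is thus unlikely to give this count, though 1 of 35 is the smallest share possible. The splits cannot tell genotype from any other difference between the 2 groups, such as stage or dissection. Chance was not excluded for the count of 12 called lists, since 8 of 35 splits called as many and the highest other called 14. Nor was it for the seed test, where 8 of 35 splits gave as small a p as 0.378 and the lowest other was 0.314. The count of lists gives no chance rate for a single list. Singly, the spongiotrophoblast, giant cell, labyrinth, transport, stress, hypoxia and natural killer cell scores had the smallest possible p. It was 0.0286 in a two-sided exact permutation test, not adjusted over the lists. For the other called lists p ran from 0.0571 to 0.257 in the same test.

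The small difference for seed-site genes did not pass the test. The values therefore cannot tell a role of untranslated region length and base content from no shift. AGCACTT ranked 101 of 630 heptamers, in the top 16.0%, GCACTTA ranked 547, and the difference against matched genes was 0.006. This does not exclude an effect on single targets or at other stages.

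Within 5 Mb of the cluster 9 of 71 genes passed the test (12.7%, against 16.2% elsewhere), an odds ratio of 0.75 (95% interval 0.327 to 1.52; Fisher's exact test, p = 0.519), with no excess of changed genes in that window as a whole. Closer in, 2 of the 13 measured genes on the list around the cluster rose and 2 fell. That share was not tested against the genes elsewhere. The mitochondrial share of counts was 4.55 ± 0.728% in wild type and 3.98 ± 0.259% in knockout (exact permutation test, two-sided p = 0.2). A retained-intron transcript of Trim2 held 3.60% of counts as a mean over the 7 libraries and one of Tor1aip1 1.65%; by gene, Trim2 held 3.87 ± 0.336% in wild type (SD, n = 3) and 3.39 ± 0.387% in knockout (SD, n = 4), and Tor1aip1 1.84 ± 0.868% and 1.58 ± 0.526%.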
